A study of Zea mays with 6 samples.

How the data were processed

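RNA was measured in 6 libraries of maize seedling shoots at the 3-leaf stage, 3 of the wild type and 3 of a Gβ knockout line. Total RNA was extracted with a plant RNA kit and sequenced as 150 bp paired-end reads, per the labels' protocols and design text. The submitters' processing notes name TopHat2, Cufflinks and Cuffdiff and the genome build B73 RefGen_v4. Versions, filters, the annotation file and the strandedness of the counting are not given in the sources used here. The authors deposited, for each library, a table of 44146 gene identifiers with FPKM values, already divided by gene length and by a library total. The unit is named in no header and was taken from the tools in the submitters' processing notes and from the values.

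The values were tested for whole reads. After a factor per library, the values of a gene in the 6 libraries were whole multiples of a step in 31928 of the 31946 genes above 0. A gene with reads in a single library meets this by construction, so only genes with reads in several libraries test it. The steps fitted whole-number gene lengths for 97.2% of the genes at the first pass (within 0.02). The other 886 genes needed a multiple, and the tolerance grew with the multiple, so that no gene could fail that step. The median length so obtained was 1781 for genes of at least 1 FPKM, and 45.3% of these lengths were multiples of 3. Reads (or read pairs) per gene were worked back from the FPKM, the lengths and the library totals. Whole multiples were taken within 0.05 of a read. A gene whose counts and length share a factor is worked back with too few reads. In simulated tables of 6000 genes with known counts, all 6 counts were recovered exactly for 98.9% of the genes with reads. The library totals behind the deposited FPKM were 0.83 to 1.14 times the recovered reads, and 0.99 to 1.00 times what median-ratio size factors of these reads would give, up to a common constant. The deposited FPKM thus followed a scaling between libraries rather than each library's own total. Genes that share reads with near-identical copies, or overlap other genes, cannot be separated with these files, so single identifiers carry that uncertainty.

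Groups and replicate numbers were taken from the sample titles. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (23232 genes, 20914 left out). Knockout was compared with wild type on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model on genotype, empirical Bayes with trend and robust settings, two-sided, Benjamini-Hochberg adjusted p below 0.05). This test, the filter, the rule for the items named and most alternatives were fixed before the data were examined. In data simulated for this comparison from the real gene means (10 draws of about 22953 genes with 200 changed, negative binomial dispersion 0.0462), 4.66% of genes changed 1.5-fold, 43.7% of those changed 2-fold, 99.4% of those changed 4-fold and 100% of those changed 8-fold were called in the right direction. Of all 1309 calls in the simulations 7.72% were false. The simulations gave every gene the same dispersion and changed far fewer genes than the 7238 called in the data. These shares therefore describe that setting and do not carry over to the real comparison. Genes found in a single genotype (at least 10 reads in every library of a group, 0 in the other), the abundance and length classes, the 100 most abundant genes and the tests of consecutive identifiers were defined after the data had been seen. Folds against a group without reads were computed against a floor of 3 reads over that group, and 95% intervals of read ratios are exact binomial. Neither covers more than counting error, since the reads of a group were pooled and the spread between replicates was left out. Read pairs are not independent molecules, so the counting error may itself be understated. Values of single libraries were compared by exact permutation tests, for which 3 against 3 gives no p below 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

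The rule for named items asked for the largest rises and falls among genes past the threshold, with a mean of at least 10 FPKM in the higher group, groups without overlap and a product name. Because the identifiers were not paired with names here, the name condition was dropped and only the first 2 rises and first 2 falls are given. The gene lists and cell type markers fixed beforehand by product name were not built for the same reason. Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, a replicate block, each library left out, and voom on the recovered reads. Because the deposited unit is FPKM, the test on log2 values was the main one, and voom was the only count-based fit run on the recovered reads.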

Results

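The study compared the transcriptomes of maize (Zea mays) seedlings of the wild type with those of seedlings in which the β subunit of the heterotrimeric G protein (Gβ) had been knocked out. Heterotrimeric G proteins consist of an α, a β and a γ subunit and relay signals from the cell surface into the cell. Shoots at the 3-leaf stage were sampled without their roots and without any treatment. Each genotype was represented by 3 libraries, described as biological replicates. Each library gave an FPKM value (fragments per kilobase of gene, divided by a library factor) for 44146 genes. The factors followed a median-ratio scaling between libraries rather than each library's own total of reads. Of the genes, 12200 were listed at 0 in all 6 libraries. The reads worked back from the FPKM values numbered 14365489, 15087864 and 16220380 in wild-type replicates 1, 2 and 3. They numbered 17310986, 15581147 and 16083058 in knockout replicates 1, 2 and 3. The genes carry B73 RefGen_v4 identifiers without names, and 0 of the 44146 identifiers matched the reference table used here. The level of the targeted Gβ gene was therefore not analysed here, nor were named pathways or cell type markers. That level would check the labels only in part, because a knockout by a small indel can leave the mRNA.

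Genotype was the main axis along which the libraries differed. The first principal component of the 23232 tested genes held 69.4% of the variance and placed the wild-type libraries between -91.0 and -83.4 and the knockout libraries between 83.7 and 88.4. Library pairs of the same genotype correlated with r of 0.88 to 0.98 across genes, and pairs of different genotype with r of 0.71 to 0.77. The most abundant transcripts showed the same order: 66 to 91 of the 100 most abundant genes were shared by 2 libraries of the same genotype, against 44 to 56 by 2 libraries of different genotype. The second component, with 20.1% of the variance, separated wild-type replicate 3 (83.8) and, to a lesser extent, knockout replicate 2 (37.8) from the other libraries of their groups, which lay between -48.6 and -11.6. In wild-type replicate 3 the 100 most abundant genes took 28.6% of the summed FPKM, against 16.7% to 18.9% in the other wild-type libraries and 16.5% to 20.9% in the knockout libraries. Replicates differed by more than sampling noise in every pair, with a mean chi-square per gene of 11.05 to 134 against an expectation of 1, so no library was a repeat deposit of another.

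**Figure D1:**
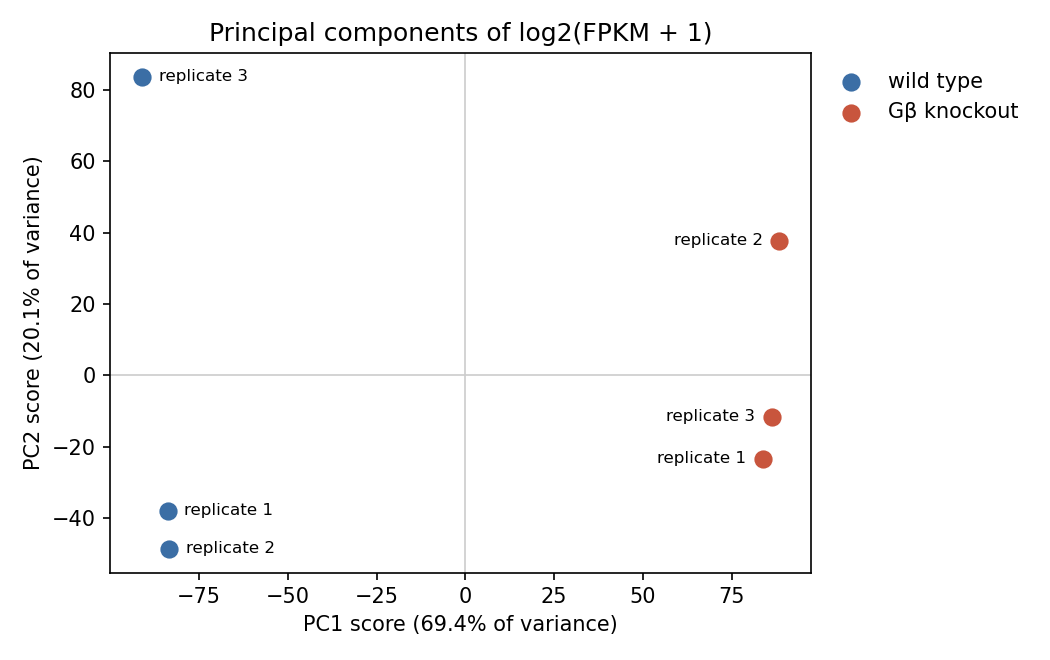
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) over 23232 genes (axes in score units, with the percentage of variance), coloured by genotype; each point is a library. The genotypes lie at opposite ends of the first component, and wild-type replicate 3 and knockout replicate 2 lie above the other libraries of their groups on the second.

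The comparison of knockout with wild type asked which transcripts differ in shoots of the Gβ knockout line. The titles name no second knockout line, so loss of Gβ cannot be told apart from other differences of that line. Of 23232 expressed genes 7238 (31.2%) passed the test, of which 3531 rose in the knockout and 3707 fell. The changes were large. A fold of at least 2 was reached by 2507 rising and 2642 falling genes, a fold of at least 4 by 995 rising and 758 falling genes, and a fold of at least 16 by 159 rising and 48 falling genes. The median log2 fold change was 1.39 among rising and -1.33 among falling genes. Over all tested genes the median was 0.02 and the median standard error 0.24. The deposited values already followed median-ratio scaling, which holds the median gene nearly level between libraries. This small median, and in part the near-even split of rising and falling genes, therefore follow from the scaling. In all 7238 called genes the 3 libraries of a genotype lay entirely above or entirely below the 3 of the other. Among all tested genes 49.4% were separated in this way, against 10% expected by chance for 3 against 3.

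Calls were made with limma on log2(FPKM + 1) at a Benjamini-Hochberg adjusted p below 0.05, and fold changes on this scale understate those of weakly expressed genes. With a pseudocount of 5 a fold of at least 2 was reached by 2932 genes in place of 5149, and weighting the libraries by their spread gave 14976 calls. The number of calls fell to 4639 without wild-type replicate 1, 4650 without knockout replicate 1 and 4212 without knockout replicate 3, the rising genes alone fell to 2325 without wild-type replicate 2, and the calls rose to 11952 without wild-type replicate 3 and knockout replicate 2, the libraries that stood apart on the second component. Scaling by the total of the recovered reads, which raised the median of all tested genes to 0.19 on the log2 scale, shifted the split from 48.8% to 60.7% rising.

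The identifiers with the largest changes had means of no more than 2.91 FPKM in the lower genotype and at least 231 FPKM in the higher. Zm00001d027524 rose from 0.077 ± 0.087 FPKM in wild type to 389 ± 74.3 FPKM in the knockout (mean ± SD, n = 3 each), a log2 fold change of 8.49 ± 0.18 (SE, limma adjusted p = 4.2e-05). It had 4 reads in the 3 wild-type libraries together and 25225 in the knockout libraries, a ratio of 5099 after scaling with a 95% counting interval of 1991 to 18717. Zm00001d031158 rose from 2.53 ± 0.56 to 1335 ± 816 FPKM, a log2 fold change of 8.42 ± 0.41 (limma adjusted p = 0.00013). Its level differed among knockout libraries, from 835 FPKM in replicate 1 to 2277 FPKM in replicate 2. In the other direction, Zm00001d030314 was among the more abundant transcripts of the wild type, at 1920 ± 1196 FPKM, and fell to 2.91 ± 1.75 FPKM in the knockout, a log2 fold change of -8.78 ± 0.68 (limma adjusted p = 0.00051). Its wild-type level ranged from 601 FPKM in replicate 3 to 2933 FPKM in replicate 1, and without wild-type replicate 3 its log2 fold change was -9.48. Zm00001d052647 fell from 231 ± 70.1 FPKM, with 4026 reads in the wild-type libraries, to no read in any knockout library. Against a floor of 3 reads over the knockout group it was at least 1660-fold lower (limma adjusted p = 7.0e-05 on the log2 scale). The intervals and the floor cover counting error only.

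**Figure D2:**
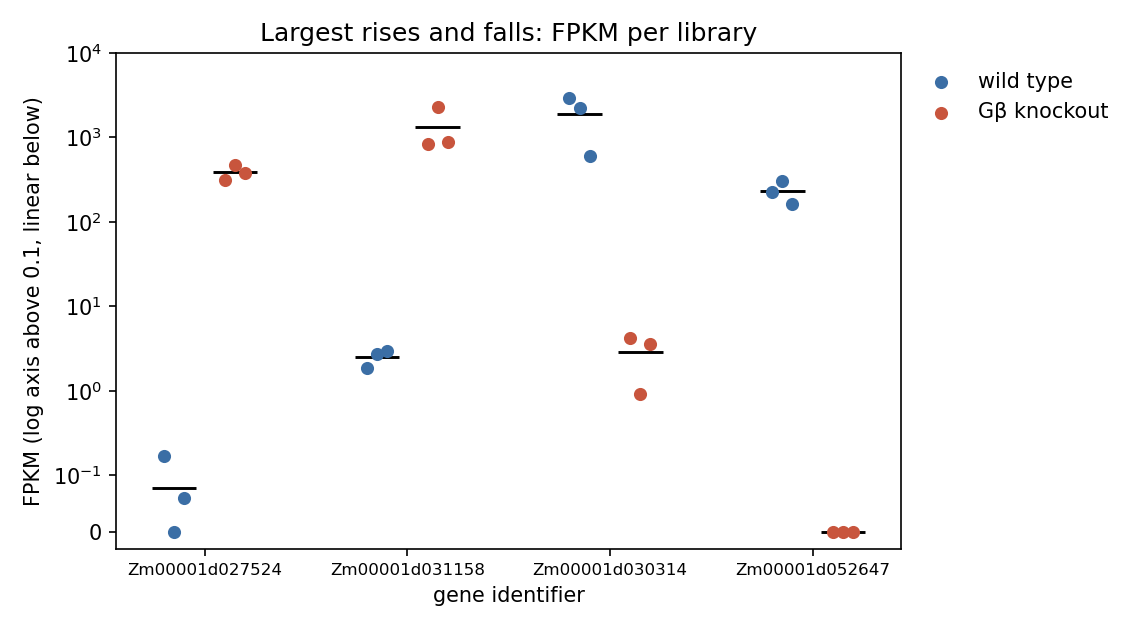
FPKM per library (log axis above 0.1, linear below) of the identifiers with the largest rises and falls that passed the test, with 3 wild-type and 3 knockout libraries each; points are libraries and bars are group means. The groups do not overlap at any of the 4 identifiers, and Zm00001d052647 lies at 0 in all knockout libraries.

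Transcripts found in a single genotype were mostly transcripts of the knockout. At least 10 reads in each of the 3 knockout libraries and none in any wild-type library were found for 191 genes, and the reverse for 29 genes. The numbers were 361 and 69 at a limit of 3 reads, and 99 and 15 at a limit of 30 reads. The knockout-only genes had a median level of 2.94 FPKM in the knockout (interquartile range 1.33 to 7.84), 35 of them reached a mean of 10 FPKM, and the highest reached 160 FPKM. Relative to a floor of 3 reads over the wild-type group, their median lower bound was a 43.7-fold rise. The wild-type-only genes had a median of 6.83 FPKM in the wild type, and 7 of the 29 reached 10 FPKM. Fewer libraries to satisfy gave more genes: 294 knockout-only genes without wild-type replicate 3, 47 wild-type-only genes without knockout replicate 2, and 368 and 59 without both libraries. Overall detection went the same way, with 28868 ± 268 genes above 0 FPKM in the knockout and 27557 ± 399 in the wild type (mean ± SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Every knockout library had more genes above 0 than every wild-type library.

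Rising and falling genes differed in how abundant they were. Among genes with a mean of up to 10 FPKM over all libraries 2199 rose and 1356 fell (61.9% of calls rising), and among genes above 10 FPKM 1332 rose and 2351 fell (36.2% rising; Fisher's exact test over genes, p = 5.6e-107, with genes not being independent replicates). The share rising went from 71.2% of calls below 3 FPKM to 29.7% between 100 and 1000 FPKM. The median log2 fold change of all genes in these classes went from 0.24 to -0.22. Of the 38 genes above 1000 FPKM, 3 rose and 5 fell. Among the 100 genes of highest mean 14 rose and 17 fell, and 36 were lower in every knockout library than in every wild-type library while 18 were higher in every one. This difference was not seen after quantile normalization, which gives all libraries the same distribution of values and so removes differences in distribution by construction. There 46.1% of calls up to 10 FPKM and 45.0% of those above it were rising (Fisher's exact p = 0.33). Other scalings apply a single factor to each library and shift all its genes nearly alike. They could move the shares but hardly remove the difference between them, so they do not test it. The shares were 72.4% and 49.0% after scaling by total recovered reads. They were 61.5% and 35.7% after median-ratio rescaling, which hardly changes values already scaled in nearly that way.

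**Figure D3:**
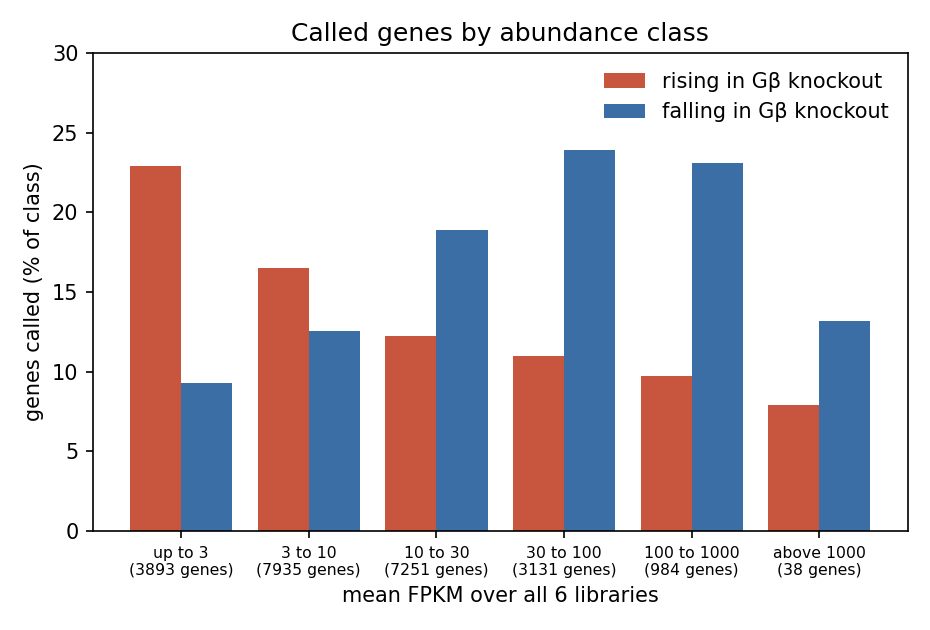
Percentage of tested genes called as rising or falling in the knockout (vertical axis) in 6 classes of mean FPKM over all 6 libraries (horizontal axis, with the number of genes in each class). Rising genes make up 22.9% of the class up to 3 FPKM and 9.76% of the class from 100 to 1000 FPKM, and falling genes 9.27% and 23.1% of the same classes.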

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

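The voom fit, the fit on 4 libraries, the scaling by total reads and the alternative limits for genes of a single genotype were chosen after seeing the data. The 4 named identifiers kept a limma adjusted p below 0.05 under every alternative (highest 0.0046). Their log2 fold changes ranged from 6.26 to 12.29 (Zm00001d027524), 7.32 to 8.89 (Zm00001d031158), -9.48 to -7.67 (Zm00001d030314) and -11.62 to -5.52 (Zm00001d052647). None of the 7238 calls changed direction (5179 tested at a mean of at least 5 FPKM). Their groups do not overlap, so only rescaling, normalization or voom could reverse one. Median-ratio rescaling, quantile normalization, a smaller pseudocount of 0.1, no filter, a plain variance model, voom on recovered reads and scaling by total reads gave between 7031 and 7554 calls. With a replicate block 4579 genes were called, 2171 rising and 2408 falling, of which 4535 were among the reported calls. Deviations of same-numbered libraries from their group means correlated at 0.15, -0.37 and -0.20, and none of the wild-type libraries correlated best with its own number, so the numbers did not pair the libraries. Leaving out each library in turn gave 4212 to 8614 calls, with 2021 to 4197 rising and 2191 to 4417 falling. Library weights raised the calls to 14976 (7501 rising and 7475 falling), and the 4 libraries other than wild-type replicate 3 and knockout replicate 2 gave 11952 (5894 and 6058); the cause was not tested for the block, the weights or the libraries left out. An adjusted p below 0.01 left 3495 calls (1656 rising and 1839 falling), 3277 of them at least 2-fold. A pseudocount of 5, which shrinks the folds of weak genes by construction, left 2932 genes at 2-fold, against 5149. A mean of at least 5 FPKM left 2105 rising genes because fewer weak genes were tested (16513 in all). Genes with reads in the knockout only numbered 361 at 3 reads, 99 at 30 reads, 368 in the 4 libraries and 203 to 294 with each library left out, and genes with reads in the wild type only 69, 15, 59 and 32 to 47. The rising share of calls up to 10 FPKM lay 25.7 percentage points over that above 10 FPKM, and 1.16 points after quantile normalization (Fisher's exact p = 0.33), which removes differences in distribution by construction. Other alternatives gave 17.0 to 29.6 points, but those that apply a single factor to each library could hardly change this difference. The planned edgeR and DESeq2 fits were not run. The gene list tests and the targeted gene were not run because the identifiers carry no names here. Simulated changes of 1.5-fold were called in 4.66% of cases.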

Other observations

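Of the tests below, the split of the libraries, the correlation of departures before correction, the test of an even background, the correlation of fold changes by identifier distance and the one for neighbours of similar length were chosen after their results were seen. In 4 classes of increasing gene length, with limits at 1110, 1788 and 3036 bases, 33.8%, 34.2%, 31.7% and 24.9% of the tested genes were called, and the median reads per library were 125, 273, 390 and 591. The difference between the classes was not tested. Among the genes at 0 in a whole genotype, 2238 were above 0 in the knockout only and 1105 in the wild type only.

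The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share below 0.05. The real division gave 7238 calls with limma and was the only 1 of the 10 to reach that number. The highest of the others gave 0 calls, and 1339 genes at an unadjusted p below 0.05 against 10046 in the real division. Each of the other divisions mixes the genotypes, so the difference between genotypes adds to the spread within their groups and their counts are not a chance level for the real one.

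More genes had reads in the knockout libraries than in the wild-type libraries. Thinning every library to the smallest total left the lowest knockout library 602 genes above the highest wild-type library, and thinning to equal reads outside the 100 most abundant genes left it 588 above, which argues against depth and a few dominant transcripts. For genes with at least 5 reads the gap was 916, while an even background in proportion to length, at the rate that would put reads into 2235 of the 14453 genes without wild-type reads, would add 31.3 genes. Genes whose length was not worked back, among them all genes without reads in any library, were given the mean length of the 2235 genes. The gain was computed on counts that were not thinned. Under these assumptions the values argue against genomic DNA as the source of that gap. They leave genes with fewer reads open. A wider range of genes transcribed in shoots lacking Gβ is a hypothesis that remains and was not tested. A difference in genetic background between the lines, or in how the groups were grown or prepared, was not tested either and remains as well.

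Wild-type replicate 3 and knockout replicate 2, which stood apart on the second component, departed from the other libraries of their groups with a correlation of r = 0.37 across 23232 genes (genes are not independent replicates). Of the 9 pairs of a wild-type and a knockout library, wild-type replicate 2 with knockout replicate 1 correlated more (0.47) and wild-type replicate 1 with knockout replicate 3 less (0.28), and because departures within 3 libraries sum to 0 these values are not independent and no chance level was computed. The first correlation was 0.369 after quantile normalization and 0.368 without the 100 most abundant genes, and the Spearman correlation was 0.463 at fixed gene length and level, against 0.475 without that correction. Differences in distribution between libraries, a few abundant genes and gene length are thus each unlikely as the whole cause. A constant scaling factor shifts the log2 values of a library nearly alike and barely moves such a correlation. The normalization was therefore no test of scaling alone. The labels give no harvest time, batch or other difference between replicates, and no biological explanation was tested.

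Genes with consecutive identifier numbers, which in this annotation mostly follow the order of genes along the chromosomes, changed together more than shuffled genes. The fold changes of 11982 consecutive pairs correlated at r = 0.106 (one-sided p = 0.001, the smallest that 1000 shuffles give, adjusted p = 0.0035 over 7 distances), falling to 0.049, 0.028 and 0.021 at distances of 2, 3 and 5 (adjusted p = 0.0035, 0.0052 and 0.0047), and 60.3% of 1251 consecutive pairs with both genes called went the same way, against 50.03% expected. Being called in either direction, at fixed level and length, correlated at 0.024 between consecutive identifiers, above its shuffled upper limit of 0.017. At distances of 10 to 200 being called correlated at no more than 0.0039 (upper limit of the shuffled range 0.025). Clustering of calls over such distances was thus not found. Which number or size of differing chromosome blocks would have been seen was not computed. Neither a limited number of long blocks nor a difference in background spread over the whole genome can therefore be excluded. Pairs whose lengths differed more than 1.5 times still gave r = 0.063, so reads shared between near-identical full-length copies do not explain those pairs. Pairs of similar length gave r = 0.187, and for these shared reads and a joint change of tandem copies cannot be told apart without sequence.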
